A study of Mus musculus with 8 samples.

How the data were processed

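The study measured gene expression in single cells of mouse liver by droplet sequencing with molecular identifiers, in 8 libraries from 4 stages and 2 cell fractions. Per the labels, each library is a group of its own. Reads were processed with Cell Ranger, version 4.0.6 per the submitters' processing notes and 6.1.2 per the file headers of the matrices, and the mm10 build is named in the submitters' processing notes. The unit of the deposited matrices is counts, whole-number UMIs per gene and barcode, with no normalization. The matrices list 32285 gene identifiers, of which 32158 occur in the GENCODE vM21 annotation used here for positions. Of 794 genes named or listed, 793 had a position.

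Barcodes were kept with at least 500 UMIs, at least 200 genes and at most 50% mitochondrial UMIs. Doublets were called in each library with Scrublet as provided in scanpy 1.11.5, at an expected rate of 0.06, and removed. It marked 207 barcodes (3.03%) in the MASH-fibrosis NPC library and between 0.02% and 0.31% in the other 7 libraries, where it has not worked. Kept cells of all libraries were clustered together on 2000 variable genes and 40 principal components, with 15 neighbours and Leiden clustering in igraph 0.11.9 at resolution 1. Mitochondrial genes and the ribosomal DNA transcripts Gm42418 and AY036118 took no part in clustering. A cluster was named after the class with the highest mean log2 fold of its markers, from marker lists of 17 classes fixed before the data were examined. It stayed unnamed with fewer than 3 markers at 2-fold, with as many markers of another class among its 10 leading genes, or when shallow with none of its own. A further rule, that leading genes of immunoglobulin-secreting cells, peritoneal macrophages or granule-forming progenitors leave a cluster unnamed, was set after the clusters had been seen. Hepatocyte-like, macrophage-like and the other names mean this match of markers only.

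UMIs were summed over the cells of a class in a library with at least 20 cells. Hepatocytes were taken from the hepatocyte fraction and all other classes from the NPC fraction. CPM were computed over nuclear-encoded genes, and log2 ratios with a prior of 1 CPM. With 1 library per group no test and no p-value was computed. CPM and folds have exact 95% Poisson and conditional binomial intervals, and shares exact Clopper-Pearson intervals, which cover counting error only. A fold against no UMI was computed as a lower bound against a floor of 3 counts. Genes were named by a rule of size fixed before the data were examined: up to 10 genes per direction and comparison with the largest log2 ratio, among those with at least 100 UMIs over the 2 libraries, 50 CPM in the higher, a 2-fold ratio, and a CPM in the higher of at least 0.5 of that of its whole library. Mitochondrial, ribosomal protein, haemoglobin, immunoglobulin, T cell receptor, Mup, Gm, Rik and sex-linked transcripts and markers of another class were left out of this ranking. Members of the gene lists are named as examples besides.

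For 32 gene lists fixed before the data were examined, the median log2 ratio was taken over members with at least 10 CPM in a stage and 20 UMIs in all, with an interval from 200 Poisson draws. Members were counted as higher or lower at a 1.5-fold ratio whose interval excluded 1. The percentile of a median comes from 10000 random lists matched on expression within 100 ranks. The method was tested on simulated data for steatosis over control in the hepatocyte fraction, with 200 changed genes. Each of these had at least 100 expected UMIs over both simulated libraries, so calls of changed genes with fewer UMIs were not tested. With no upper limit on their abundance, 90.0% to 100% of the changed genes were called. So were 8.26% of 6413 unchanged genes, because the changes moved the total by -0.27 log2. A list of 15 genes with 2-fold changes had a median of 0.72. After this result a second simulation kept changed genes below 200 CPM. It called 92.0% to 100% of them and 1.94% of 6607 unchanged genes, and the list had a median of 1.01. Intervals covered the true ratio in 95.3% and 95.5% of genes. The simulated counts were Poisson draws with no variation between cells or mice, so this coverage was built in.

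Alternatives were at least 1500 UMIs, at most 20% mitochondrial UMIs, doublets kept, resolution 2, each library clustered alone, scaling by trimmed mean of M-values (TMM), mitochondrial UMIs in the total, equal weight per cell, a prior of 10 CPM, list members from 50 CPM, hepatocyte-like cells of the NPC fraction, and subtraction of the library's pooled profile. Leaving out the ribosomal DNA transcripts and omitting the mitochondrial filter were added after the data had been seen. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0 and matplotlib 3.10.9. A few genes are not reported here.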

Results

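Single-cell RNA sequencing was used to follow mouse liver through 4 stages, which the labels call control, steatosis, MASH (metabolic dysfunction-associated steatohepatitis) and MASH-fibrosis. Control mice ate the diet labelled SD and the other stages the AMLN diet. At each stage the liver was perfused, dissociated and split into a hepatocyte fraction depleted of CD45-positive cells and a fraction of non-parenchymal cells (NPC), and live cells were sorted, per the labels' protocols. This gave 8 libraries, 1 for each stage and fraction. The labels give 2 mice per group and do not say how they were pooled. No difference between stages therefore has a replicate check, no test between stages was possible, and every interval is a 95% interval that covers counting error only. The labels give no diet duration for each library.

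The deposited matrices held between 3108 and 12205 barcodes per library. Total UMIs (unique molecular identifiers, 1 per captured transcript molecule) in the hepatocyte fraction were 52872186 in control, 29473212 in steatosis, 24989252 in MASH and 45085056 in MASH-fibrosis. In the NPC fraction they were 57040435, 18815456, 15742704 and 91078697 in the same order. After filtering, 5932, 1613, 5893 and 4876 barcodes remained in the hepatocyte fraction and 4876, 2874, 4945 and 6620 in the NPC fraction. Median UMIs per kept barcode in the NPC fraction ranged from 952 in MASH to 10054 in MASH-fibrosis, so shares and rare transcripts of the MASH NPC library rest on far shallower cells. Barcodes with over 50% mitochondrial UMIs made up 51.3% of the control and 50.7% of the steatosis hepatocyte fraction, against 28.6% in MASH and 39.9% in MASH-fibrosis. With filtering, median UMIs per barcode of the hepatocyte fraction fell from 3282 to 814 in control and from 7038 to 1540 in steatosis. They fell from 2389 to 1624 in MASH and from 1929.5 to 912 in MASH-fibrosis. Kept barcodes of this fraction held 8387013, 6845874, 13019307 and 18114545 UMIs in the order of stages.

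The makeup of the NPC fraction differed between stages. Hepatocyte-like cells were 9.02% (exact binomial interval 8.23 to 9.86) of kept barcodes in control, 24.98% (23.4 to 26.6) in steatosis, 65.2% (63.8 to 66.5) in MASH and 3.69% (3.25 to 4.17) in MASH-fibrosis. With no mitochondrial filter, control (30.8%) lay above steatosis (28.2%). Macrophage-like cells were 11.4% (10.6 to 12.4), 9.71% (8.65 to 10.8), 3.86% (3.34 to 4.44) and 30.9% (29.7 to 32.0) in that order. Endothelial-like cells made up 50.1%, 28.5%, 6.90% and 49.2%, and stellate-like or fibroblast-like cells 17.8%, 11.7%, 1.44% and 2.66%. Of the barcodes with a class name other than hepatocyte in the same libraries (4150, 1524, 710 and 5942), macrophage-like cells were 13.4% (12.4 to 14.5), 18.3% (16.4 to 20.3), 26.9% (23.7 to 30.3) and 34.4% (33.2 to 35.6). On this denominator endothelial-like cells were 58.9%, 53.7%, 48.0% and 54.8%, and stellate-like or fibroblast-like cells 20.9%, 22.05% (19.99 to 24.2), 10.0% (7.89 to 12.4) and 2.96% (2.55 to 3.43). The MASH values on this denominator depended on the clustering: over 6 other settings macrophage-like cells were 12.3% to 58.0%, endothelial-like cells 17.4% to 59.7% and stellate-like or fibroblast-like cells 2.82% to 11.0%, so the place of MASH in the order of stages is not set. Neutrophil-like cells were 2.12% (1.78 to 2.49) of the MASH-fibrosis library and at most 0.263% of the other NPC libraries. Of named non-hepatocyte barcodes they were 0.241%, 0.459%, 1.83% (0.978 to 3.11, 13 cells) and 2.36% (1.99 to 2.77), so that MASH and MASH-fibrosis overlapped. In the hepatocyte fraction, hepatocyte-like cells were 99.5% in control, 90.7% in steatosis, 83.9% in MASH and 96.8% in MASH-fibrosis.

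These shares also carry the centrifugation, the CD45 depletion, the live-cell sort and the depth of each library, so they are shares of recovered barcodes and not of the liver. Unnamed barcodes were 5.87% of the control, 21.99% of the steatosis, 20.5% of the MASH and 6.56% of the MASH-fibrosis NPC library. A cluster led by Jchain and C1q transcripts was kept out of the macrophage class by a rule set after the clusters had been seen. It held 1.56%, 6.16%, 16.2% and 1.56% of the 4 NPC libraries. With each library clustered alone the macrophage-like share of the MASH NPC library was 16.1%, and at clustering resolution 2 it was 17.6%, against 3.86% in the joint clustering.

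**Figure D1:**
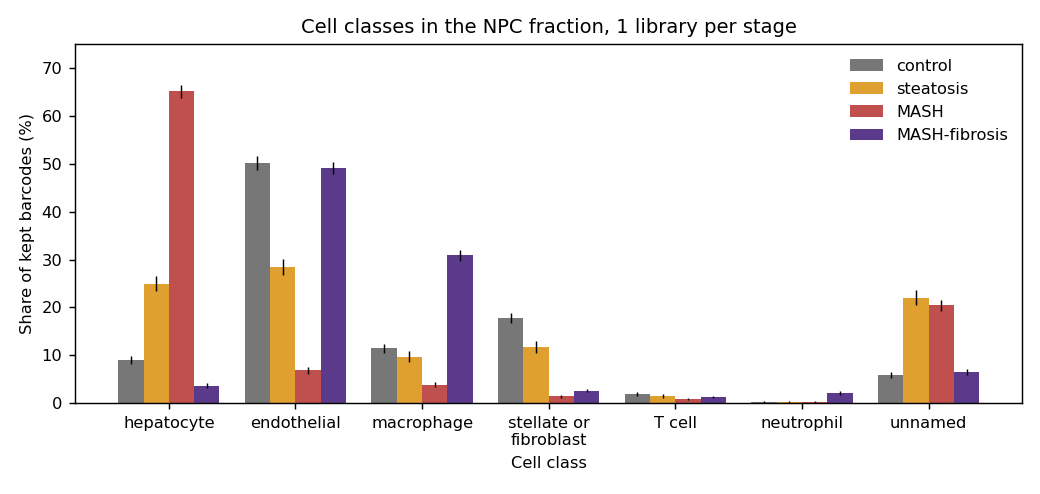
Share of selected cell classes and of unnamed barcodes, in percent of kept barcodes, in the NPC library of each stage, with exact binomial intervals that cover counting error only. Hepatocyte-like cells reached 65.2% of the MASH NPC library, and macrophage-like cells 30.9% of the MASH-fibrosis NPC library.

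Expression was compared as CPM, the UMIs of a gene summed over the cells of a class and scaled to the same total in every library. Hepatocyte-like cells came from the hepatocyte fraction, 5904 in control, 1463 in steatosis, 4945 in MASH and 4721 in MASH-fibrosis. They fell mostly into stage-specific clusters, numbered 3 and 4 in control, 14 and 18 in steatosis, 2, 6 and 13 in MASH, and 0 in MASH-fibrosis. The median UMIs of these hepatocyte-like cells were 812, 1395, 1675 and 892 in the order of stages. Their median mitochondrial shares were 17.07%, 10.85%, 15.83% and 3.35%, so cell quality also differed between stages. Summed UMIs weigh deep cells more: 163 cells of cluster 24 held 31.5% of them in control, 159 of cluster 33 held 57.5% in steatosis and 231 of cluster 28 held 48.9% in MASH-fibrosis. A few very abundant transcripts took different shares of the total, and the median log2 ratio to control over all measured genes was 0.87 in steatosis, -0.45 in MASH and 0.42 in MASH-fibrosis. A 1.5-fold ratio is 0.58 in log2, so in steatosis a gene at the all-gene median already had the ratio that counts as higher. Counts of higher genes there do not by themselves set a list apart. The share of all genes counted as higher or lower is not given here. The list medians of these cells are therefore also given relative to all genes, after subtraction of the median of the comparison. The percentile of a list is its place among 10000 random lists of the same size and similar expression. Of the 20 lists measured in hepatocytes, 8 in steatosis, 9 in MASH and 10 in MASH-fibrosis lay in the highest or lowest 2.5% of their random lists. The lists described were picked after all list medians had been computed.

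In steatosis, hepatocyte-like cells had far higher levels of fatty acid synthesis transcripts than in control. All 16 measured members of the de novo lipogenesis list were at least 1.5-fold higher. The list's median log2 ratio was 3.45 (3.33 to 3.58), at percentile 100, and 2.58 relative to all genes. Scd1, which desaturates newly made fatty acids, stood at 5859 CPM against 214 (27.4-fold, 26.0 to 28.9). Fasn, the fatty acid synthase, was 32.7-fold higher (25.4 to 42.7). Srebf1, which encodes the transcription factor that drives these genes, stood at 367 CPM against 6.44, and Aacs, which activates acetoacetate for lipid synthesis, at 112 against 1.20 (93.7-fold, 47.2 to 218). The liver pyruvate kinase gene Pklr was 32.8-fold higher. In the gluconeogenesis and glycolysis list, 8 of 14 measured genes were higher and none lower. The median was 1.31, and 0.44 relative to all genes, which is under a 1.5-fold difference. Abcg5 and Abcg8, whose products export sterols into bile, were 18.6-fold and 14.7-fold higher, and 6 of 8 sterol efflux genes were higher, 1 lower.

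Fatty acid oxidation transcripts were lower in steatosis hepatocytes. Of 22 genes on the fatty acid oxidation and ketogenesis list, 14 were lower, 2 higher and 6 neither, with a median of -0.79 and -1.65 relative to all genes (percentile 0.61). The fatty acid hydroxylase genes Cyp4a14 and Cyp4a10, known targets of PPAR-alpha, stood at 49.5 and 69.8 CPM against 3048 and 2251 in control. Ehhadh, of peroxisomal oxidation, was at 65.0 CPM against 468. Cpt1a, which lets fatty acids into mitochondria, was 1.92-fold higher. This was close to the all-gene median log2 ratio of 0.87, so relative to all genes it hardly differed. Acute phase genes were also lower, 10 of 20 against 2 higher, among them Saa1 (60.1 against 1521 CPM) and Saa2 (22.9 against 792). So were 5 of 10 interferon response genes, with Isg15 at 5.72 CPM against 36.4, and 20 of 30 nuclear-encoded oxidative phosphorylation genes (median -0.83, -1.69 relative to all genes). The interferon list had a median of -0.70, -1.57 relative to all genes, and in hepatocyte-like cells of the NPC fraction its direction was opposite, at 0.82. Transcripts of the circadian clock differed too. An index took the median log2 ratio of 7 clock output genes minus that of 2 activators, Arntl and Clock. It was 1.62 (1.38 to 2.05) in steatosis hepatocytes. Dbp stood at 53.3 CPM against 28.2 and Per2 at 40.1 against 3.60, and of the output genes only Nr1d1 was not higher (33.5 against 38.2). Arntl stood at 7.71 CPM against 8.39 and Clock at 59.45 against 41.19.

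MASH hepatocytes had lower fatty acid oxidation transcripts and higher lipogenic transcripts than control hepatocytes. On the fatty acid oxidation and ketogenesis list 17 of 22 genes were lower, none was higher and 5 were neither, with a median of -1.34 (-1.43 to -1.28), -0.89 relative to all genes, at percentile 0.12. Cyp4a14 stood at 57.6 CPM and Ehhadh at 43.0. Of 15 measured lipogenesis genes 10 were higher and 2 lower, with a median of 0.72 and 1.17 relative to all genes. Srebf1 was 21.2-fold (15.6 to 29.5), Scd1 15.1-fold (14.3 to 15.9) and Fasn 11.9-fold (9.25 to 15.6) above control. Serpina7, which encodes the thyroxine-binding globulin, was 24.6-fold higher (14.5 to 45.4).

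Of 17 pericentral genes 7 were higher in MASH, 3 lower and 7 neither, with a median of 0.51, under a 1.5-fold difference, and 0.96 relative to all genes, at percentile 100. Glul, the pericentral glutamine synthetase, stood at 846 CPM against 144. Periportal genes were lower in 11 of 18 and higher in 2, with a median of -0.77 that was -0.32 relative to all genes, less than a 1.5-fold difference. Asl, of the urea cycle, was at 483 CPM against 1217. Immediate early genes had a median of -1.68 (-1.23 relative to all genes) with 7 of 11 lower and none higher, and Fos stood at 3.49 CPM against 25.6. Interferon response genes had a median of -1.31 (-0.86 relative) with 6 of 9 lower, although in hepatocyte-like cells of the NPC fraction that median was 0.32. The metallothionein gene Mt1 stood at 33.8 CPM against 1325. Gm42418, a transcript that overlaps ribosomal DNA, took 26.8% of the UMIs of nuclear genes in the MASH hepatocyte fraction against 4.94% in control. Lars2 (10181 CPM against 871), Camk1d (9.15-fold) and Gphn (7.19-fold) were higher in the same cells. With the ribosomal DNA transcripts left out, the median over all genes was 0.04 and that of the oxidation list -0.90.

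MASH-fibrosis hepatocytes combined high acute phase, sterol synthesis and lipogenic transcripts with low oxidation and periportal transcripts. Acute phase genes were higher in 19 of 21 and lower in none, with a median of 1.51 (1.49 to 1.56), percentile 100, and 1.09 relative to all genes. Saa2 stood at 15584 CPM against 792 (19.7-fold, 19.1 to 20.2), Orm2 was 29.4-fold higher (27.0 to 32.2), and Lcn2, an iron-siderophore binding protein of inflammation, 18.1-fold (16.8 to 19.6). Cholesterol synthesis and uptake genes were higher in 18 of 20 and lower in none, with a median of 1.65 and 1.24 relative to all genes. Fdps, of the mevalonate pathway, was 12.0-fold higher, and Insig1, which retains the SREBP complex in the endoplasmic reticulum, 10.2-fold. Lipogenesis genes were higher in 14 of 16 with a median of 1.86 and 1.45 relative to all genes, but in the 244 hepatocyte-like cells of the NPC fraction that median was -1.10.

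Hepatocyte injury and reprogramming genes were higher in 10 of 11 and lower in none in MASH-fibrosis, with a median of 1.49 and 1.08 relative to all genes. Spp1, which encodes osteopontin, was 17.4-fold higher (12.2 to 25.7) and Ly6d 12.3-fold. Anxa2, at 48.7 CPM, had only 2 UMIs in control, a ratio of 163 with an interval of 44.9 to 1346. Pericentral genes were higher in 11 of 17 with a median of 0.97 (0.56 relative), which was -1.19 in hepatocyte-like cells of the NPC fraction, and Glul was 7.06-fold higher. Periportal genes were lower in 11 of 18 and higher in none, with a median of -1.01 (-1.43 relative). Asl was at 0.163 of control and Hal, which degrades histidine, at 0.221. On the oxidation list 16 of 22 genes were lower and none higher, with a median of -1.08 (-1.49 relative), and Cyp4a14 and Cyp4a10 stood at 1.92 and 3.51 CPM. Fabp5, a fatty acid carrier, was 43.3-fold higher (31.2 to 61.9), and Lpl, the lipoprotein lipase, 58.2-fold (29.4 to 135). Cxcl14, a chemokine, and Prtn3, a neutrophil protease, stood at 61.1 and 57.3 CPM against 0.30 and 0.45 in control, where they had 2 and 3 UMIs (ratio intervals 56.3 to 1686 and 43.5 to 619). Elane, another protease of the same granules, had 6 UMIs in these MASH-fibrosis hepatocytes against 864 of Prtn3.

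**Figure D2:**
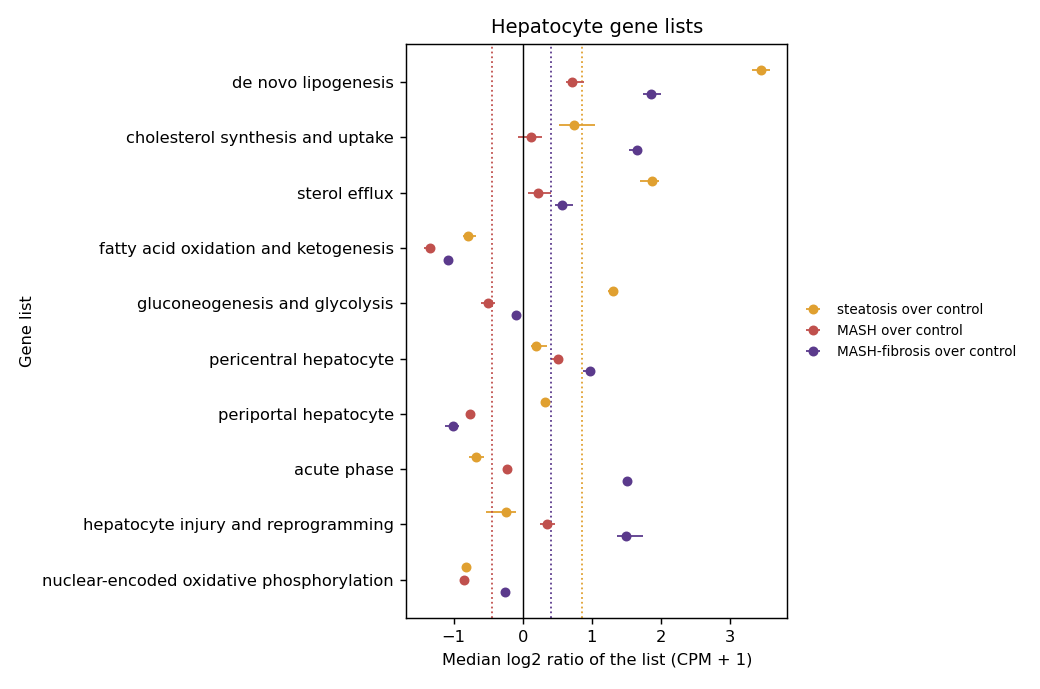
Median log2 ratio to control of each described gene list in hepatocyte-like cells of the hepatocyte fraction, with counting intervals as bars and the median of all genes as dotted lines for each stage. Lipogenesis lay at 3.45 in steatosis, 0.72 in MASH and 1.86 in MASH-fibrosis, the last of which was -1.10 in hepatocyte-like cells of the NPC fraction.

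Between successive stages, MASH hepatocytes had lower lipogenic and glucose transcripts than steatosis hepatocytes. The median of all genes was -1.11 in this comparison, itself beyond a 1.5-fold difference. Counts of lower genes do not by themselves set a list apart here. Lipogenesis genes were lower in 15 of 16 with a median of -1.7, which was -0.59 relative to all genes, and Elovl6, which lengthens fatty acids, stood at 50.1 CPM against 636. Gluconeogenesis and glycolysis genes were lower in 12 of 15 and higher in 1, with a median of -2.04 and -0.93 relative to all genes. Pck1, the gluconeogenic carboxykinase, was at 662 CPM against 2731. Cholesterol synthesis had a median of -1.08 that became 0.03 relative to all genes. Acute phase genes were higher in 9 of 21 and lower in 1, and injury genes were higher in 5 of 9 and lower in none, with a median of 0.82 (1.94 relative to all genes) that was -0.23 in hepatocyte-like cells of the NPC fraction. The growth factor receptor gene Egfr stood at 279 CPM against 4520, Onecut1 at 9.01 against 341 and Malat1, a nuclear noncoding RNA, at 943 against 16154.

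MASH-fibrosis hepatocytes had higher acute phase, immediate early, injury and cholesterol synthesis transcripts than MASH hepatocytes. Of 21 acute phase genes 20 were higher and none lower, with a median of 1.32 and 0.52 relative to the all-gene median of 0.81. That all-gene median itself exceeds a 1.5-fold difference, so counts of higher genes do not by themselves set a list apart here. Saa2 was 268-fold higher (246 to 294), Saa1 85.7-fold and Lcn2 68.7-fold. All 14 measured immediate early genes were higher (median 1.84, 1.03 relative), with Fos at 55.9 CPM against 3.49. All 11 injury genes were higher (median 1.5, 0.69 relative), as were 18 of 20 cholesterol genes (median 1.57, 0.76 relative). Lipogenesis had a median of 1.22, with 11 of 16 genes higher, and -1.22 in hepatocyte-like cells of the NPC fraction. Relative to all genes its median was 0.41, under a 1.5-fold difference. Fabp5 was 92.5-fold higher, and Prtn3, with no UMI in MASH, at least 159-fold higher against a floor of 3 counts in that library.

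The 2 fractions each held hepatocyte-like cells, so the genes named in the hepatocyte fraction could be looked up in the NPC fraction. The cells of the NPC fraction are a second look at the same mice and not replicates. The named genes are those with the largest ratios in the hepatocyte fraction, so a shared direction was likely from the start. All 20 named genes had the same direction in the NPC fraction in each of the 5 comparisons. The difference was at least 2-fold there for 20 of 20 in steatosis, 19 in MASH and 20 in MASH-fibrosis against control, for 18 in MASH against steatosis and for 20 in MASH-fibrosis against MASH. The hepatocyte-like cells of the NPC fraction were few in MASH-fibrosis, 244 at a median of 1226 UMIs. Most of them lay in cluster 17, while cluster 0 held most hepatocyte-like cells of the hepatocyte fraction. In the control NPC library, 137 cells of cluster 24 held 91.95% of the summed UMIs of 440 hepatocyte-like cells. The median mitochondrial share of these cells was 15.89% in the control and 0.29% in the MASH-fibrosis NPC library.

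Macrophage-like cells of the NPC fraction, 558 in control, 279 in steatosis, 191 in MASH and 2043 in MASH-fibrosis, had higher lipid-associated transcripts in summed UMIs at each diet stage and lower Kupffer cell transcripts in MASH and MASH-fibrosis. Lipid-associated macrophage genes had median log2 ratios to control of 0.77 in steatosis, 1.54 in MASH and 2.19 (1.96 to 2.38) in MASH-fibrosis, each at percentile 100. With equal weight per cell these medians were 0.08, 0.77 and 1.90. The median of all genes in these cells was -0.11 in MASH and -0.12 in MASH-fibrosis, which put the list at 1.65 and 2.30 relative to it. Its genes were higher in 12 of 22, 17 of 23 and 18 of 23 and lower in 1, 1 and none. Gpnmb, a lysosomal glycoprotein gene, stood at 1.51 CPM in control, 43.2 in steatosis, 468 in MASH and 542 in MASH-fibrosis, the last 359-fold above control (154 to 1105). Trem2, which encodes a lipid-sensing receptor, stood at 36.6 CPM in control and 536 in MASH-fibrosis (14.7-fold, 12.3 to 17.7). Mmp12, which degrades elastin, was higher than in control at each diet stage, at 272, 981 and 388 CPM against 20.2. Fabp5, Lgals1 and Cd63 were 97.1-fold, 102-fold and 36.6-fold higher in MASH-fibrosis, and Spp1 53.2-fold.

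Kupffer cell identity genes were lower in 8 of 17 in steatosis, 12 of 17 in MASH and 10 of 17 in MASH-fibrosis, and higher in none, 1 and none. The medians were -0.52, under a 1.5-fold difference, -1.72 and -0.66. Cluster 8, the unnamed one led by Jchain and C1q transcripts, was not in these sums. Its leading genes include Folr2 and Cd5l of this list and Mmp12 of the lipid-associated list. It held 801 cells of the MASH NPC library, against 191 macrophage-like cells. At resolution 2 and with each library alone, no compared list median of at least 1.5-fold changed direction. The largest moves over all classes were 0.54 and 1.7, so the size of the MASH medians may depend on leaving it unnamed. Cd163, a haemoglobin scavenger receptor, stood at 1078 CPM in control and 227, 48.6 and 142 at the diet stages. Clec4f, a Kupffer cell lectin, was at 3690 CPM in control and 2574, 947 and 2331. Timd4, which binds phosphatidylserine on dying cells, was at 0.258 of control in MASH-fibrosis. The B cell chemokine gene Cxcl13 stood at 512 CPM in control and 23.6, 7.36 and 15.8. Recruited monocyte genes had medians of 0.87, 3.47 and 2.46, higher in 3 of 6, 6 of 8 and 7 of 9, and Ccr2, the monocyte chemokine receptor, stood at 13.9 CPM in control and 59.0, 166 and 80.8. No barcode of any library was named as a monocyte, so monocytes within this class were not told apart from changed expression in macrophages. Chst11 had no UMI in control and 194 CPM in MASH, at least 214-fold higher. Class II antigen presentation genes had medians of 0.72, 1.46 and 0.70 with 5, 7 and 6 of 7 higher, but with equal weight per cell the values in steatosis and MASH were -0.18 and -0.14. Proliferation genes had medians of 1.41 in steatosis, -0.05 in MASH and 2.14 in MASH-fibrosis, where all 15 were higher, with Top2a at 100.5 CPM against 19.3. Inflammatory cytokine genes had medians of -0.46, -0.73 and -0.01, and Il1b stood at 219 CPM in control against 41.0, 48.6 and 63.2.

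Most macrophage-like cells lay in clusters 15 and 12 in control, 12 in steatosis and MASH, and 7 and 15 in MASH-fibrosis. In MASH, 161 cells of cluster 12 had a median of 819 UMIs and held 29.6% of the summed UMIs of the class. The 23 cells of cluster 7 (median 17733) held 57.6% and the 7 of cluster 15 (median 11192) 12.8%, so the summed values of MASH macrophages rest mostly on these few cells. In steatosis 23 cells of cluster 7 held 25.8% and 41 of cluster 15 held 37.3%. The median depth of the class was 5479, 4582, 874 and 20588 UMIs in the order of stages. In MASH-fibrosis this exceeded the 8453 of endothelial-like cells in the same library. Doublet calling worked only in that library, where it removed 207 barcodes, so undetected doublets remain open for these cells.

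**Figure D3:**
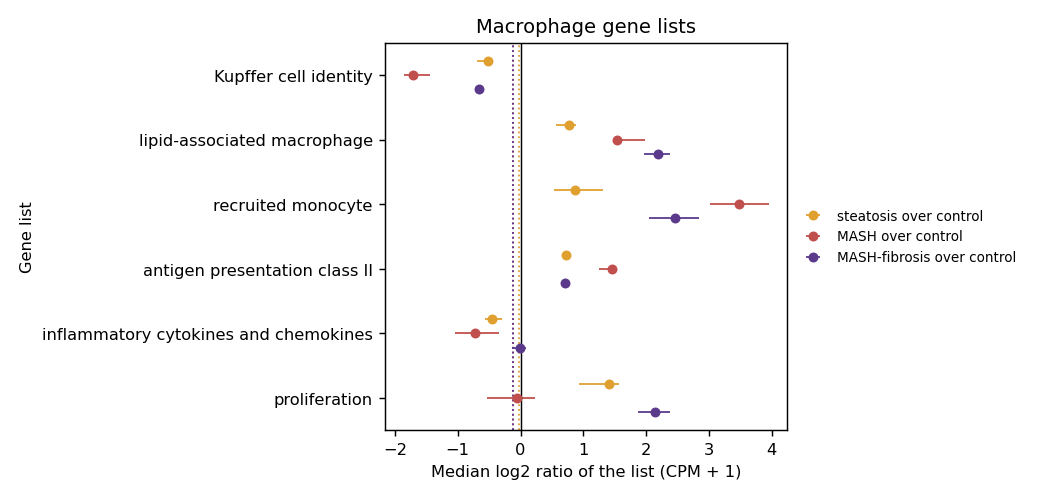
Median log2 ratio to control of the described gene lists in macrophage-like cells of the NPC fraction, with counting intervals. Lipid-associated genes lay at 0.77, 1.54 and 2.19 and Kupffer cell genes at -0.52, -1.72 and -0.66 in steatosis, MASH and MASH-fibrosis, while with equal weight per cell lipid-associated genes were at 0.08 in steatosis and class II genes turned to -0.18 and -0.14 in steatosis and MASH.

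**Figure D4:**
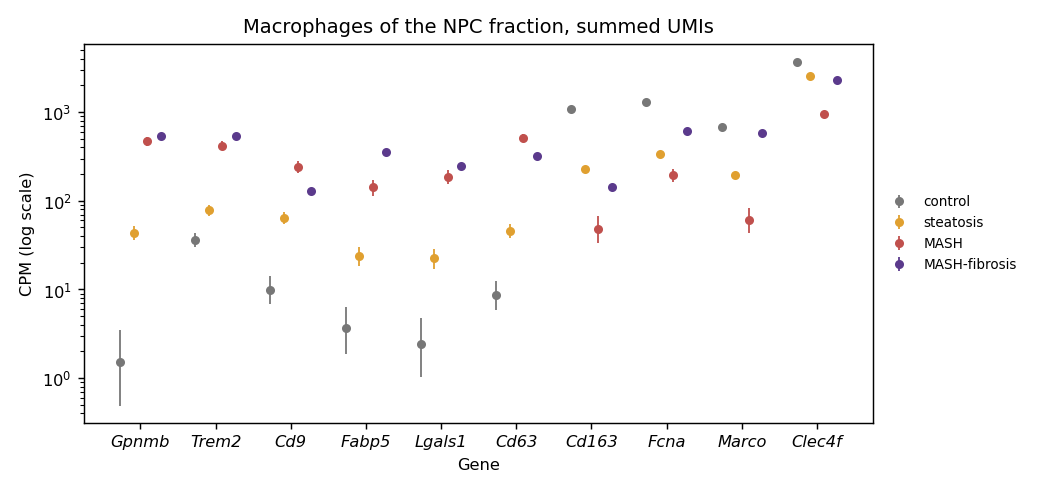
CPM of named genes in macrophage-like cells of the NPC fraction at each stage on a log axis, with exact Poisson intervals. Gpnmb stood at 1.51 in control and 542 in MASH-fibrosis, and Cd163 at 1078 and 142.

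Endothelial-like cells (2444, 819, 341 and 3255 in the NPC fraction) had higher activation and capillarisation transcripts in steatosis and MASH-fibrosis. The list medians were 0.77 in steatosis, 0.50 in MASH, under a 1.5-fold difference, and 1.10 (1.07 to 1.15) in MASH-fibrosis, each at percentile 100. In steatosis 11 of 18 genes were higher and none lower, and in MASH 8 of 18 were higher and 1 lower. In MASH-fibrosis 15 of 19 genes were higher and none lower, and the median was 0.98 relative to the all-gene median of 0.12. Esm1, a marker of angiogenic endothelium, was 3.87-fold, 7.03-fold and 8.21-fold higher in the order of stages. Fabp4, a fatty acid carrier of capillaries, was 4.82-fold, 2.74-fold and 3.83-fold higher. Selp, which tethers leukocytes, was 4.73-fold higher in MASH-fibrosis (3.97 to 5.66), Ackr1, of venules, 6.78-fold, and Cd34, of capillaries, 3.34-fold. Sinusoidal identity genes had medians of 0.01, -0.26 and 0.28, with 12, 13 and 11 of 18 neither higher nor lower. Interferon response genes were higher in 14 of 18 in steatosis (median 0.99) and in 8 of 18 in MASH and in MASH-fibrosis, and Cxcl10 was 3.91-fold, 2.42-fold and 2.45-fold higher. Zbtb16 was at 0.317, 0.161 and 0.094 of control. Oxidative phosphorylation genes were higher in 19 of 30 in steatosis, none in MASH and 25 in MASH-fibrosis. Clusters 1 and 10 held most of these cells in steatosis and MASH, cluster 1 in control, and clusters 5 and 1 in MASH-fibrosis. Cluster 5 held 13.5% of the summed UMIs of the class in control, 49.1% (190 cells) in steatosis, 25.8% (39 cells) in MASH and 69.6% in MASH-fibrosis.

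Stellate-like or fibroblast-like cells carried high matrix transcripts in MASH-fibrosis. Activation and matrix genes were higher in 21 of 25 and lower in none there, with a median of 1.53 (1.44 to 1.7) at percentile 100. The median was 0.30 in steatosis, with 14 of 22 neither, and -0.24 in MASH, with 16 of 21 neither. Acta2, the smooth muscle actin of myofibroblasts, stood at 518 CPM in MASH-fibrosis against 0.65 in control, where it had 4 UMIs (interval of the ratio 312 to 2950). Col1a1, a chain of type I collagen, was at 1009 CPM against 60.9 (16.6-fold, 14.8 to 18.6), and Timp1, which inhibits matrix proteases, was 71.4-fold higher (39.2 to 145). Tagln was 36.8-fold higher and Lox, which crosslinks collagen, 24.2-fold (12.0 to 55.2). Quiescence genes had medians of -0.03, -1.28 and -0.51, lower in 3, 11 and 6 of 15. Hgf, the hepatocyte growth factor gene, stood at 2197 CPM in control and 1792, 455 and 894. The cells numbered 869, 336, 71 and 176, with clusters 19, 21 and 16 in control, 16 in steatosis and MASH, and 19 in MASH-fibrosis. Of the 71 MASH cells, 66 of cluster 16 held 33.8% of the summed UMIs, and 3 of cluster 21, 1 of cluster 43 and 1 of cluster 19 held 44.8%, 11.7% and 9.72%, so the summed MASH values rest mostly on these few cells. With equal weight per cell the quiescence median in MASH was -2.07. The 71 cells had a median of 689 UMIs and carried macrophage and endothelial transcripts, with Mpeg1 5.04-fold and Fabp4 8.10-fold above control.

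T-cell-like cells were few (91, 42, 43 and 87) and had higher effector transcripts than control in MASH and MASH-fibrosis. No barcode of any library was named as a natural killer cell or innate lymphoid cell. A changed mix of cells within this class was therefore not told apart from changed expression. Effector genes had medians of 0.44, 0.96 and 1.78, higher in 4 of 13, 7 of 14 and 13 of 17, but 0.20 in MASH over steatosis and 0.32 in MASH-fibrosis over MASH. Ccl4, a chemokine of activated T cells, was 57.3-fold higher in MASH (30.6 to 121) and 24.9-fold in MASH-fibrosis (13.3 to 52.5). In MASH-fibrosis the coreceptor gene Cd8a was 9.39-fold higher (5.30 to 18.1), the checkpoint receptor gene Pdcd1 18.1-fold (6.78 to 68.0) and Tox, an exhaustion-linked factor, 4.0-fold (3.41 to 4.71). Naive T cell genes had medians of 0.00, -0.28 and -0.99, with 5 of 8 lower in MASH-fibrosis. Zbtb16, a factor of innate-like T cells, stood at 16.5 CPM there against 288, but it was also lower in endothelial-like cells of that stage.

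Positions of the genes named most often follow the mouse annotation GENCODE vM21, on the mm10 build named in the submitters' processing notes. Scd1 (ENSMUSG00000037071) lies on chromosome 19 from 44394455 to 44407879, Fasn (ENSMUSG00000025153) on chromosome 11 from 120805846 to 120824547 and Cyp4a14 (ENSMUSG00000028715) on chromosome 4 from 115486200 to 115496142. Saa1 (ENSMUSG00000074115) lies on chromosome 7 from 46740497 to 46742980, Gpnmb (ENSMUSG00000029816) on chromosome 6 from 49036546 to 49070929 and Acta2 (ENSMUSG00000035783) on chromosome 19 from 34241090 to 34255590. All are annotated as protein coding, and UMIs were counted per gene.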

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

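All tests of explanations in this part were chosen after the results they concern had been seen, and no difference between the fractions was itself tested.

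Several lists had opposite directions in the hepatocyte-like cells of the 2 fractions. The interferon response list in steatosis over control had a median log2 ratio of -0.70 in the hepatocyte fraction and 0.82 in the NPC fraction. In MASH-fibrosis over control, lipogenesis stood at 1.86 and -1.10 and pericentral genes at 0.97 and -1.19. In MASH-fibrosis over MASH, lipogenesis stood at 1.22 and -1.22. The NPC fraction of MASH-fibrosis held 244 hepatocyte-like cells.

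Some clusters that carry no class name took larger shares than in the control library of the same fraction. Cluster 8, led by Jchain, Fabp7 and C1qb, made up 6.16% (5.31 to 7.10) of the steatosis and 16.2% (15.2 to 17.3) of the MASH NPC library, against 1.56% in control. Cluster 11, led by Nrgn, Ctla2a and Gng11, a mix of platelet and endothelial transcripts, was 15.6% (14.2 to 16.9) of the steatosis NPC library against 3.84% in control. In the MASH-fibrosis NPC library, cluster 34, with Alox15 and Lyz1, was 1.45% against 0.410% in control, and cluster 36, with Elane and Prtn3, was also 1.45% against 0.062%.

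Lipogenic transcripts in steatosis hepatocytes were weighed for depth, for time of day or feeding, and for diet stage. Depth and a few dominant transcripts as the whole cause are argued against by the lowest list median among TMM scaling, barcodes of at least 1500 UMIs and NPC-fraction hepatocytes, which was 2.54. A different time of day or feeding state remains a candidate explanation: an index of clock output genes minus clock activators differed from control in the same direction in hepatocytes (1.62, 1.38 to 2.05), endothelial cells (3.13) and stellate cells (1.86), though its intervals included 0 in macrophages (-0.11) and T cells (0.74). The diet stage itself stays open, because the orders of the index and of lipogenesis over the stages only partly match. The hepatocyte index was 0.15 in MASH and -3.05 in MASH-fibrosis, where lipogenesis was also above control. In MASH-fibrosis the index had the same direction in stellate cells (-0.93, -1.65 to -0.48). It had the opposite direction in endothelial cells (0.53, 0.32 to 0.71), and its interval included 0 in macrophages (0.02, -0.26 to 0.45). Both explanations may hold together, and the labels give no collection time. Neither was weighed for the lower fatty acid oxidation transcripts, which were compared with the same control library at every stage, so both stay open there too.

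Gm42418 took 26.8% and 28.5% of the UMIs of nuclear genes, mitochondrial ones left out, in the MASH libraries, against at most 7.38% in the 6 libraries of other stages. Shallow barcodes as the cause are argued against by barcodes of at least 1500 UMIs, where the lower of the MASH over control ratios of the fractions was 3.77. The excess may lie mainly in hepatocytes, whose ratio was 6.13, since the lowest ratio of 5 classes was 1.39 in endothelial cells, under the bound of 1.5. Macrophages (1.87), stellate cells (2.25) and T cells (2.26) lay above that bound, and after subtraction of the pooled profile, computed once these ratios were known, the ratios were 1.08 in endothelial cells, 1.30 in macrophages, 1.66 in stellate cells and 2.02 in T cells. A preparation batch and the stage cannot be told apart, because the labels name no batch.

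Prtn3, Fabp5, Lpl and Cxcl14 in MASH-fibrosis hepatocytes were weighed for free RNA or doublets from 1 source class each. These were the progenitor cluster with Elane for Prtn3, macrophages for Fabp5 and Lpl, and stellate cells for Cxcl14. The levels that class markers in these hepatocytes would allow were exceeded 12.9 times for Lpl, the lowest, and 191 times for Prtn3. This argues against these classes as their source. For Fabp5 and Cxcl14 the ratios were 275 and 3141. But the macrophages and stellate cells held only 352 and 106 CPM of them, against 233 and 61.1 in the hepatocytes. A high ratio was therefore likely from the start. Other classes were not tried as sources. The NPC-fraction hepatocytes of the same stage had 96.0 CPM of Prtn3, 355 of Fabp5, 115 of Lpl and 32.5 of Cxcl14. No biological explanation was tested, reads shared with neighbouring genes were not examined, and the stage itself stays open with 1 library per fraction.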

How the results depend on the processing

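Leaving out the ribosomal DNA transcripts and omitting the mitochondrial filter were chosen after seeing the data, as were the 10 leading results whose values are given below; the other alternatives were planned. For these 10, a value is given where it left the counting interval of the reported value. No paired analysis was possible because each group has 1 library and no result comes from a test. Of 90 list medians taken for this check, 56 were at least 1.5-fold. The effector medians of T cells between successive stages and the list medians under other observations were not among the 90. Over 14 alternatives these gave 716 values, of which 708 had the same direction, 667 were still at least 1.5-fold and 8 had the opposite direction. Some alternatives left too few cells or genes for a value, so that clustering each library alone gave 53 of the 56 medians, 1500 UMIs 55 and list members from 50 CPM 50. The alternative with hepatocyte-like cells of the NPC fraction gave 32 values, 6 of them in the opposite direction. Subtraction of the pooled profile gave 22. In hepatocyte-like cells of the NPC fraction, the interferon list was 0.82 in steatosis and 0.32 in MASH, lipogenesis -1.10 and pericentral genes -1.19 in MASH-fibrosis over control, lipogenesis -1.22 in MASH-fibrosis over MASH and injury genes -0.23 in MASH over steatosis. With equal weight per cell, class II genes in macrophages were -0.18 in steatosis and -0.14 in MASH. The cause was not tested for these or for the values that follow, beyond what each alternative changes by construction.

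Lipogenesis in steatosis (3.45) was 2.98 with 1500 UMIs, 3.82 with 20% mitochondrial UMIs, 2.54 with TMM, 3.88 with equal weight per cell, 2.67 with a prior of 10 CPM, 2.56 in the NPC fraction and 2.81 with no mitochondrial filter. Fatty acid oxidation in MASH (-1.34) was -1.49 with 1500 UMIs, -0.96 with TMM, -1.20 with the larger prior, -1.27 from 50 CPM, -1.74 in the NPC fraction and -0.90 without ribosomal DNA transcripts. Acute phase in MASH-fibrosis over control (1.51) was 1.37 with 1500 UMIs, 1.80 with 20% mitochondrial UMIs, 1.11 with TMM, 1.65 with mitochondrial UMIs in the total, 1.58 with equal weight, 0.91 in the NPC fraction, 1.48 without ribosomal DNA transcripts and 1.16 with no mitochondrial filter. Over MASH (1.32) it was 1.26, 1.43, 0.58, 1.55, 1.5, 0.90, 0.84 and 1.15 in the same order, and 1.27 from 50 CPM. Lipogenesis in MASH over steatosis (-1.7) was -1.80 with 1500 UMIs, -0.61 with TMM, -1.61 with equal weight, -1.53 with the larger prior, -1.62 from 50 CPM, -1.59 in the NPC fraction and -1.23 without ribosomal DNA transcripts.

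Lipid-associated genes in MASH-fibrosis macrophages (2.19) were 2.44 with TMM, 1.90 with equal weight and 1.81 with the larger prior. Endothelial activation (1.10) was 1.07 with 1500 UMIs and also with 20% mitochondrial UMIs, 1.17 with mitochondrial UMIs in the total, 1.5 with equal weight, 1.27 with the pooled profile subtracted and 1.05 without ribosomal DNA transcripts. Stellate matrix genes (1.53) were 1.40 with doublets kept, 1.39 with equal weight, 1.41 with the larger prior and 2.46 with the pooled profile subtracted. The hepatocyte-like share of the MASH NPC library (65.2%) was 66.7% with 20% mitochondrial UMIs, 69.7% at resolution 2 and 68.0% with no mitochondrial filter. The macrophage-like share of the MASH-fibrosis NPC library (30.9%) was 32.5% with 1500 UMIs, 32.3% with doublets kept, 32.4% at resolution 2 and 32.3% with each library alone. The control NPC library had 30.8% hepatocyte-like cells with no mitochondrial filter, against 9.02%. In the NPC fraction depth limits MASH most, where 191 macrophages and 71 stellate cells had medians of 874 and 689 UMIs. MASH hepatocytes of the hepatocyte fraction had the highest median UMIs of the 4 stages (1675), but Gm42418 took 30.3% of their nuclear UMIs. Kept barcodes of that library had a median of 466 genes, against 346 in control, 751 in steatosis and 459 in MASH-fibrosis.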

Other observations

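The genes in this part were picked after their values had been seen, and none has a test. Oxidative phosphorylation genes encoded in the nucleus were higher in MASH-fibrosis in macrophage-like cells, 21 of 30 with a median log2 ratio of 0.81, and in stellate-like or fibroblast-like cells, 22 of 30 with 0.77, and none was lower. The MASH-fibrosis NPC library was also the deepest. The chaperone gene Hspa5, of the endoplasmic reticulum, was 5.37-fold higher in endothelial-like cells of that stage (5.07 to 5.68). Proliferation genes in T-cell-like cells were lower in 8 of 8 in MASH (median -2.70) and in 6 of 9 in MASH-fibrosis (median -1.37). The 43 MASH cells held 178532 UMIs of nuclear genes, against 454573 in the 91 control cells. Members could therefore pass the filter of 20 UMIs through control counts, which favours members that are lower in MASH. How many control cells carried these UMIs is not given here. Hist1h2ap, a replication-dependent histone gene, stood at 414 CPM in control against no UMI in MASH, at least 24.6-fold lower. In steatosis 7 of 11 interferon response genes were higher in T-cell-like cells, with a median of 0.89.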
